A study of Mus musculus with 2 samples.

How the data were processed

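Single-cell RNA sequencing was carried out on 2 mouse libraries with colon as the tissue label, 1 labelled WT and 1 labelled KO for Runx3. The values analysed are raw UMI counts per gene and cell barcode, deposited as 1 sparse matrix per library. Cell Ranger 8.0.1 made the matrices, per the file headers. The genome build was mm10 and Seurat 3 was used, per the submitters' processing notes. The labels' protocols describe a microwell chip with barcoded magnetic beads, whereas the barcodes in the deposited count files have 16 bases, a length used by droplet kits, and the sources do not settle which chemistry was used. The files hold barcodes already called as cells, and any further filter before deposit is not given in the sources used here. Each file lists 55357 features, of which 52081 gene identifiers match GENCODE M21, the source of the coordinates given. Counts of the 901 symbols that occur more than once were kept apart by gene identifier.

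Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 25% of UMIs from mitochondrial genes. Scrublet, as included in scanpy, was run per library with its automatic threshold. That threshold marked 0% of WT barcodes and 0.0181% of KO barcodes, outside the range of 0.5% to 15% set for it, so the barcodes with the highest 5% of scores were left out instead, 457 from WT and 319 from KO. The kept cells of both libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0 gave 28 clusters. A cluster was named after 1 of 19 classes, as X-like, from marker lists fixed in advance. The scoring rule was revised after the data had been seen. The rule used takes the class with the highest mean marker level, each marker relative to its highest cluster, and asks for a mean of at least 0.2 and for 3 markers found in at least 10% of the cluster's cells. A cluster stayed unnamed when another class had more markers among its 10 leading genes, when another class with a marker among them had more markers found, when its depth was low and none of its leading genes was a marker of its class, or when its doublet score was at least 2 times the mean. It named 19 clusters and left 9 unnamed. The 6 classes with at least 20 cells in each library were compared gene by gene.

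Raw counts were summed per library and class and expressed as UMIs per 1000000 (CPM). The ratio of the library labelled KO over WT is given as log2 after adding 5 CPM to both. Intervals are 95% intervals, exact Poisson for sums and exact binomial (Clopper-Pearson) for shares, and cover counting error only. No test, p-value, standard error or number of changed genes is given, because there is 1 library per group and cells are not replicates. Genes are named by size. Eligible genes have at least 50 UMIs over both libraries and a UMI in at least 5% of the cells of 1 library in the class, or 1% for all cells. The 12 highest and 12 lowest ratios are named over all cells, the 6 highest and 6 lowest in T, NK, fibroblast and macrophage or monocyte-like cells, and the 3 highest and 3 lowest in other classes. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, unnamed, Xist and Y-linked genes were left out of that ranking. Runx3, Runx1, Runx2 and Cbfb are named whatever their value, as are the largest and most changed members of the fixed lists. For each of 23 gene lists, the median log2 ratio of the members with at least 20 UMIs is set against 10000 random lists of the same size matched on mean expression. Its percentile describes these libraries and is not a test. The marker lists, gene lists, filters, naming of genes and most alternatives were fixed before the data were examined.

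Cells were called male-type with a UMI of at least 1 of the 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y and none of Xist, female-type with a UMI of Xist and none of those genes, and both-type with UMIs of Xist and of a Y-linked gene. These calls were added after the data had been seen. Alternatives changed 1 choice at a time: a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial), no mitochondrial limit, no doublet removal or 10% left out, resolutions 0.5 and 2, each library clustered alone, clustering without 67 genes that differ between the libraries, and a per-cell gate on at least 2 markers. The others were cells thinned to 1000 UMIs, scaling without mitochondrial genes and the 50 most abundant genes, scaling by the median gene ratio, pseudocounts of 1 and 20 CPM, a minimum of 200 UMIs, male-type cells alone, female-type cells of the library labelled KO alone, no both-type cells, and clusters of a class weighted alike or taken alone.

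The comparison was tested on simulated data with 200 changed genes drawn into counts of the real libraries. Over all cells (11607 genes), 97 of 100 genes planted at a log2 ratio of 1 and 99 of 100 planted at 2 were among the 200 largest. In NK-like cells (6730 genes), 72 and 100 of 100 were, and in macrophage or monocyte-like cells (8864 genes), 99 and 100 of 100. The median estimates over all cells were 0.78 and 1.66, below the planted values, because of the pseudocount. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.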

Results

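The series asks how RUNX3, a transcription factor of cytotoxic lymphocytes, bears on natural killer (NK) cell infiltration in colorectal cancer, with mice lacking the gene and tumour models. The data are 2 single-cell libraries with colon as the tissue label, 1 labelled WT and 1 labelled KO. The WT library holds 8800 barcodes with 85367638 UMIs and a median of 8559.5 UMIs per barcode. The library labelled KO holds 6573 barcodes with 62465176 UMIs and a median of 8074. After filtering, 8343 and 5194 cells remained, with medians of 8281 and 9350.5 UMIs and of 2751 and 2919 genes. With 1 library per group, no difference below has a replicate check, and every interval covers counting error only. The number of animals behind each library and the tumour model are not given in the sources used here.

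Runx3 transcripts were present in the library labelled KO, and the highest level of any class compared was in its NK-like cells. Runx3 (ENSMUSG00000070691, chromosome 4, 135120652 to 135177990 on the plus strand, mm10) had 255 CPM over all WT cells (251.6 to 259) and 192 CPM over all cells of the library labelled KO (188 to 196), a log2 ratio of -0.40. In NK-like cells, the level was 691 CPM in WT (659 to 725) and 846 CPM in the library labelled KO (787 to 908), 1.22 times as high (1.12 to 1.33). T-like cells had 393 and 279 CPM, a log2 ratio of -0.49, and macrophage or monocyte-like cells had 212 and 166 CPM, a log2 ratio of -0.34. Dendritic-like cells had 295 and 296 CPM, mast or basophil-like cells 269 and 280 CPM. Fibroblast-like cells, which should lack the gene, had 17.6 and 22.4 CPM. Within the T-like clusters, the log2 ratios were -0.083 in cluster 10, -0.11 in cluster 20 and -0.34 in cluster 13. Genes of the same family or complex had log2 ratios over all cells of 0.20 for Runx1, -0.28 for Runx2 and 0.11 for Cbfb, which encodes the partner subunit of RUNX proteins. In T-like cells, the ratios of Runx1 (0.49) and Runx2 (-0.46) were about as large as that of Runx3.

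A UMI of Runx3 was found in 69.8% of WT cells and 63.2% of cells of the library labelled KO. With every cell thinned to 1000 UMIs, which left out 184 and 155 shallower cells, the shares were 21.6% and 16.6%. NK-like cells gave 91.1% and 90.9% before thinning, 46.1% and 50.5% after it, at median depths of 5881.5 and 7182 UMIs. The background from free RNA in fibroblast-like cells was 14.6% and 20.5% before thinning, at median depths of 15019 and 21073 UMIs, and 0.858% and 1.81% after it. The counts are per gene and the deleted part of Runx3 is not given in the sources used here. Tags from outside the deleted part check nothing, so these counts do not settle the label. The library is therefore called the library labelled KO throughout, and each direction drawn from it is that of the label.

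**Figure D1:**
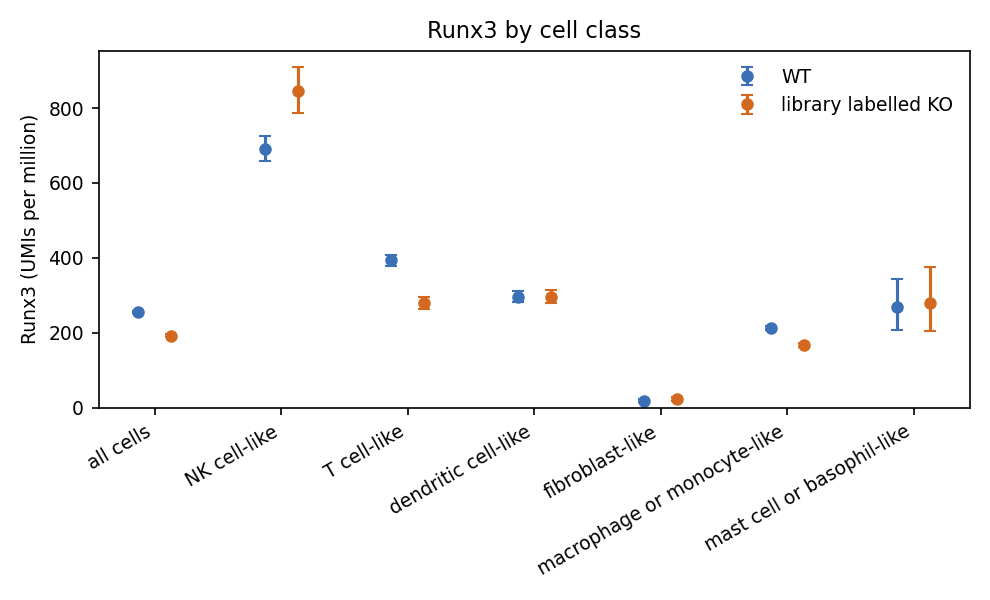
Runx3 in UMIs per 1000000 (vertical axis) for all cells and the 6 classes compared, in WT (blue) and the library labelled KO (orange), with exact Poisson 95% intervals as bars. NK-like cells stand highest in both libraries, at 691 and 846 CPM, and fibroblast-like cells lowest, at 17.6 and 22.4 CPM.

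NK-like cells made up 4.03% of WT cells (336 cells, 3.62 to 4.47%) and 1.91% of the library labelled KO (99 cells, 1.55 to 2.32%), a ratio of 0.473 (0.374 to 0.594). T-like cells made up 14.0% (13.3 to 14.8%) and 9.61% (8.82 to 10.4%), a ratio of 0.684 (0.615 to 0.760). Macrophage or monocyte-like cells were the largest class in both libraries, at 38.6% and 40.4%, and dendritic-like cells had the same share of 6.45% in each. Fibroblast-like cells made up 2.79% and 3.20%, mast or basophil-like cells 0.479% and 0.501%. Neutrophil-like cells were few in WT, 14 cells or 0.168% (0.0918 to 0.281%), and more frequent in the library labelled KO, 102 cells or 1.96% (1.60 to 2.38%). The markers of this class include S100a8 and S100a9, which differ between the libraries. Its ratio of 11.7 was 11.6 after clustering without the 67 differing genes, while the NK-like ratio was then 0.496. Those genes were left out of the clustering only, and the clusters were still named with all markers. This alternative therefore does not test the naming.

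The NK-like share was lower in the library labelled KO against each reference class tried. There were 28.7 NK-like cells per 100 T-like cells in WT and 19.8 in the library labelled KO, 62.5 and 29.6 per 100 dendritic-like cells, and 10.4 and 4.72 per 100 macrophage or monocyte-like cells. With fibroblast-like cells left out of the total, the NK-like share was 4.14% and 1.97%. A gate on NK markers without Cd3 genes, applied cell by cell, found 3.44% and 1.83%, which is below its background from free RNA of 3.86% and 6.63% in the deeper fibroblast-like cells. Thinned to 1000 UMIs, it found 2.26% and 1.07%, shares that lie within the intervals of its background, 2 of 233 (0.104 to 3.07%) and 1 of 166 fibroblast-like cells (0.0153 to 3.31%). The thinned background itself, 0.858% and 0.602%, lies below the gate's shares but rests on 2 cells and 1 cell. The gate therefore leaves the share of NK cells undecided. Within the library labelled KO, NK-like cells made up 2.11% of female-type cells and 1.84% of male-type cells (23 of 1250, 1.17 to 2.75%), against 4.30% of the male-type cells of WT (285 of 6629, 3.82 to 4.82%). The neutrophil-like ratio became 5.04 with female-type and 27.8 with male-type cells, subsets that hold 24 and 21 of the 102 neutrophil-like cells of that library, since many had no sex call. The WT side of the male-type ratio is 4 cells, so its interval is wide (9.39 to 112).

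Some clusters were kept out of every class by the naming rule, which was revised after the data had been seen. These 9 clusters held 33.4% of WT cells and 36.0% of cells of the library labelled KO. Cluster 5, led by Arg1 and Cxcl1, held 10.7% and 15.5%, cluster 3, led by Ear2 and Mgl2, 10.5% and 3.79%, and cluster 8, led by Cxcl3 and Slpi, 0.276% and 4.31%. Cluster 9 held 4.82% and 3.77%, cluster 11 4.71% and 2.77%, and cluster 6 0.443% and 2.91%. Clusters 3, 5, 6, 9 and 11 scored highest for macrophage or monocyte markers, so the shares and ratios given for that class leave them out. Cluster 14, led by Il17a and Trdc, held 1.27% and 1.33%, cluster 23, led by Ctsk and Acp5, 0.396% and 0.828%, and cluster 27, led by immunoglobulin genes, 0.276% and 0.732%. A cluster mostly of 1 library, such as clusters 6 and 8, may be that library rather than a cell type. At least 3 of 9 epithelial marker genes were found in 0 of 8343 WT cells and in 1 of 5194 cells of the library labelled KO. Single markers were found in leukocyte clusters, with Cdh1 in 48.0% and Epcam in 24.9% of cells of the dendritic-like cluster 21.

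**Figure D2:**
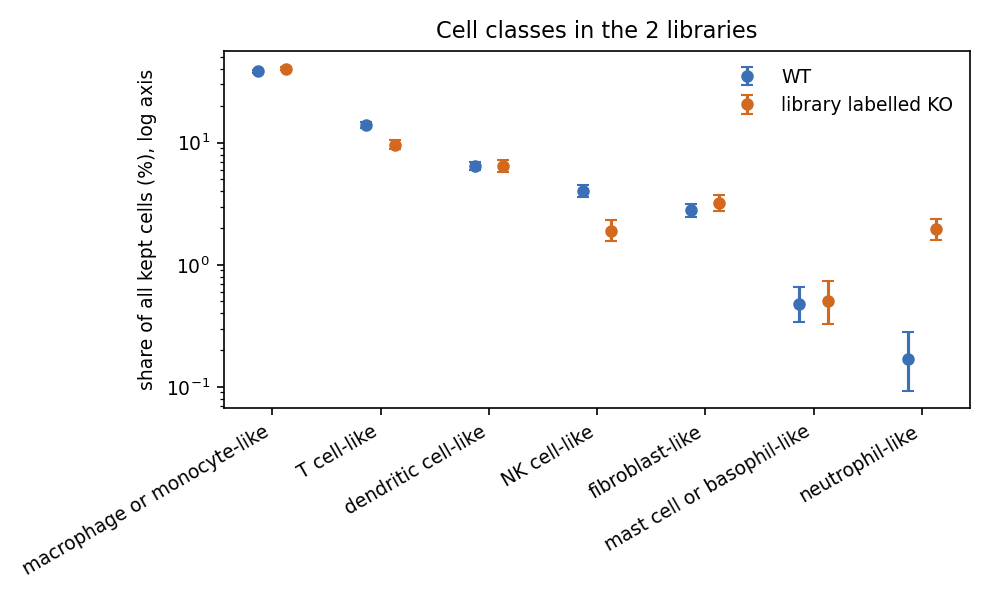
Share of all kept cells in percent (vertical log axis) for each named class, in WT (blue) and the library labelled KO (orange), with exact binomial 95% intervals as bars. NK-like cells lie at 4.03% and 1.91%, T-like cells at 14.0% and 9.61%, and neutrophil-like cells at 0.168% and 1.96%.

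Over all cells, the library labelled KO had more transcripts of neutrophil and inflammatory genes and fewer of cytotoxic granule genes. The highest ratios belonged to Jchain (10.6 and 186 CPM, log2 3.62), which joins secreted antibodies, to Cxcl3 (26.1 and 291 CPM, log2 3.25), a chemokine that attracts neutrophils, and to S100a9 (log2 3.02), Slpi (3.01) and S100a8 (2.92), which neutrophils and activated myeloid cells make. G0s2 (2.52), Serpinb2 (2.28), Csf3 (2.19), Saa3 (2.08), Inhba (2.08), Retnlg (1.72) and Ccl3 (1.67) followed. The lowest ratios included the granzymes Gzmf (71.4 and 18.0 CPM, log2 -1.73), Gzmd (-1.12), Gzma (-1.06) and Gzme (-1.05), the NK receptor Klre1 (-1.09) and the granule protein Nkg7 (184 and 89.0 CPM, log2 -1.01). Tagap1 (-1.16), Asgr2 (-1.16), Ms4a4b (-1.08), the lysozyme gene Lyz2 (-1.06), Nrgn (-1.05) and Tmem163 (-1.03) were also among the 12 lowest.

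Some of these genes lie mostly in 1 cluster of both libraries. Cluster 24, which is neutrophil-like, held 98.3% of the S100a9 UMIs of WT and 95.7% of those of the library labelled KO. The NK-like cluster 12 held 72.6% and 84.0% of Gzma UMIs and 79.3% and 91.5% of Gzmd UMIs. Cluster 27 held 98.6% and 99.1% of Jchain UMIs, and Jchain also differed within it, at 4429 and 20774 CPM. Cxcl3 was higher in the library labelled KO both within cluster 8, which held 15.1% and 70.7% of its UMIs, at 2052 and 5570 CPM, and outside it, at 22.2 and 88.5 CPM.

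Of the 30 measured NK and cytotoxic effector genes, 28 were lower and 2 higher over all cells of the library labelled KO, with a median log2 ratio of -0.57 at percentile 0 of the random lists. T cell inhibitory receptors were lower in 13 of 14 members (median -0.23, percentile 0), among them Pdcd1 with 31.7 and 15.1 CPM. The residency and RUNX3-linked lymphocyte genes were lower in 16 of 25 (median -0.08, percentile 8.19), with log2 ratios of -0.92 for Cd8a and 0.57 for Klf2. Klf2 was also among the leading genes of the unnamed cluster 6, which held 0.443% of WT cells and 2.91% of the library labelled KO. Cytokines that attract NK and T cells were higher in 10 of 18 (median 0.11, percentile 99.7), with Ccl2 at 514 and 1087 CPM and Ccl4 at 415 and 1146 CPM. Ligands of NK receptors were higher in 6 of 13 (median -0.01, percentile 60.4).

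Antigen presentation and interferon genes were lower over all cells, and inflammatory genes were higher. Of the interferon response list, 30 of 32 members were lower (median -0.32, percentile 0), of MHC class II presentation 11 of 12 (median -0.38, percentile 0), with Cd74 at 12396 and 8999 CPM, and of MHC class I presentation 14 of 15 (median -0.24, percentile 0.02). The macrophage inflammatory list was higher in 17 of 20 (median 0.93, percentile 100), and the epithelial antimicrobial and inflammation list in 13 of 15 (median 0.89, percentile 100), led by S100a9 and S100a8, whose UMIs lay mostly in the neutrophil-like cluster 24. Dissociation and immediate early genes, a list meant to follow the handling of cells, were also higher in 17 of 22 (median 0.30, percentile 100). Whether handling raised them was not tested.

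Genes of cancer-associated fibroblasts and matrix were higher over all cells in 24 of 27 (median 0.33, percentile 100), a median that was 0.088 with male-type and 0.077 with female-type cells alone, subsets that leave out most fibroblast-like cells for want of a sex call. Genes of the epithelial to mesenchymal transition were higher in 29 of 33 (median 0.28, percentile 100), with Fn1 at log2 0.66, in libraries where 1 cell had 3 epithelial markers. TGF beta and BMP targets were higher in 14 of 21 (median 0.12, percentile 99.9), and WNT targets and intestinal stem genes in 11 of 16 (median 0.05, percentile 97.47), a median that was -0.015 with female-type cells alone. Absorptive colonocyte genes were higher in 6 of 9 (median 0.05, percentile 93.2), oxidative phosphorylation genes in 14 of 25 (median 0.07, percentile 95.9). Goblet and secretory genes were lower in 6 of 8 (median -0.04, percentile 9.91), cytokines of stroma and lymphoid niche in 7 of 10 (median -0.04, percentile 15.2). The epithelial to mesenchymal median was 0.12 within fibroblast-like, 0.34 within T-like, 0.15 within dendritic-like and -0.01 within NK-like cells. Fibroblast-like cells held 3979965 of 75985424 UMIs in WT and 4017600 of 54840008 in the library labelled KO.

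Per NK-like cell, the effector list as a whole was at a similar level in both libraries, while some granzymes outside it were lower in the library labelled KO. Of 29 measured effector genes, 18 were higher and 11 lower (median 0.07, percentile 93.1). Perforin (Prf1) had 555 and 517 CPM, Gzma 1263 and 1247 CPM, Gzmc 8290 and 8932 CPM, and Ncr1, an activating receptor of NK cells, 295 and 314 CPM. The inhibitory receptor gene Klrc1 had a log2 ratio of 0.62, the chemokine genes Ccl5 and Xcl1 0.54 and 0.52, and the interferon gamma gene Ifng 0.43. Of the 4 granzymes outside the list, chosen after their values had been seen, Gzmf was lower with 1119 and 491 CPM and Gzmg with 393 and 218 CPM, while Gzmd had 1291 and 1191 CPM and Gzme 532.1 and 531.5 CPM. Residency and RUNX3-linked genes were higher in 13 of 21 (median 0.05, percentile 87.6), T cell inhibitory receptors in 9 of 13 (median 0.22, percentile 99.8), and interferon response genes were lower in 24 of 29 (median -0.42, percentile 0). Tissue-resident and regulatory macrophage genes were lower in 10 of 12 (median -1.02, percentile 0), MHC class II genes in 9 of 12 (median -0.64, percentile 0). The part of macrophage RNA in the interferon median was not separated.

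The largest ratios within NK-like cells rest on few cells or on transcripts of other cells. The 6 lowest were Lyz2 (879 and 170 CPM, log2 -2.34), Ccl6 (-2.24), Pid1 (-2.21), Cybb (-1.97), Tbxas1 (-1.96) and Ms4a6c (-1.90). Among the 6 classes, Ccl6 was highest in mast or basophil-like cells and the other 5 in macrophage or monocyte-like cells, and Ms4a6c came to 0.15 without doublet removal. The 6 highest were the collagen gene Col3a1 (2.42), Fabp5 (1.65), Ccl1 (1.42), H2ac8 (1.13), Prss2 (1.12) and Cd200r1 (1.12), on 99 cells in the library labelled KO. In male-type cells alone, Fabp5 came to -0.26, Ccl1 to -1.11, H2ac8 to -2.73 and Prss2 to -1.73, on at most 9 UMIs of each gene in 23 cells of the library labelled KO, and the inhibitory receptor median to -0.23. Fabp5 also came to -0.14 without both-type cells.

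**Figure D3:**
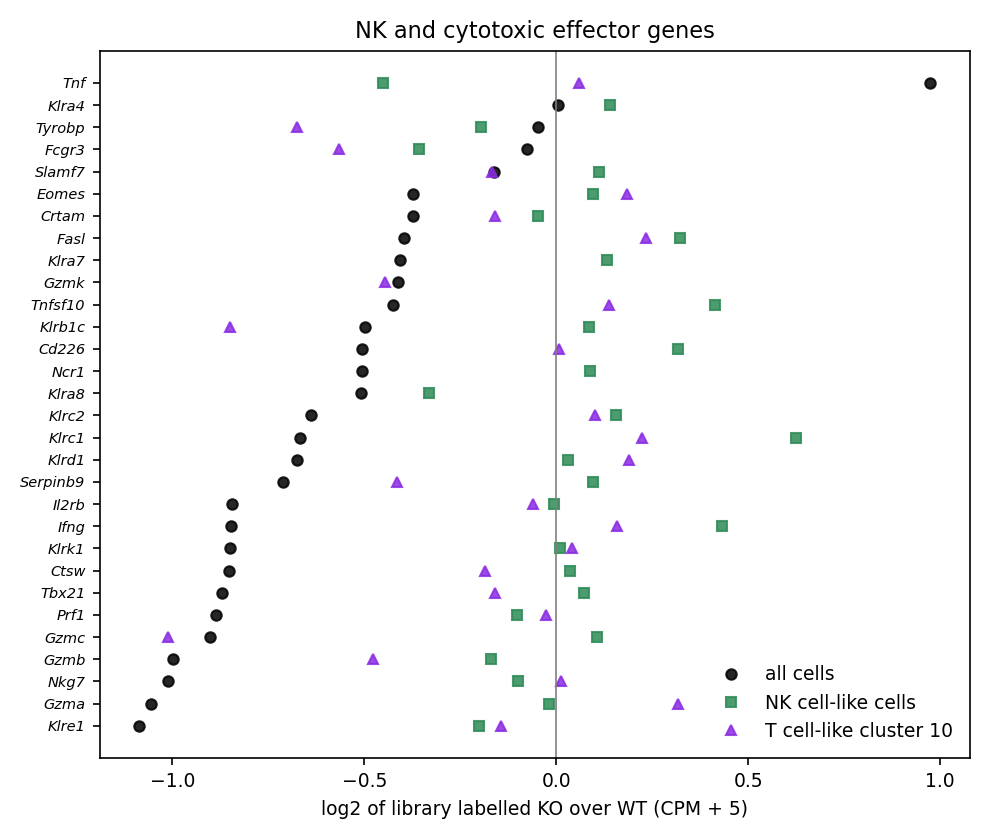
Log2 ratio of the library labelled KO over WT (horizontal axis) for each gene of the NK and cytotoxic effector list, over all cells (black circles), in NK-like cells (green squares) and in T-like cluster 10 (purple triangles). Over all cells 28 of 30 genes lie below 0, while in NK-like cells 18 of 29 lie above 0.

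T-like cells of the library labelled KO had fewer transcripts of granzymes, but the libraries filled this class with different clusters. Cluster 10, with CD8 T cell genes, held 6.98% of WT cells and 2.52% of the library labelled KO, and cluster 20, with the regulatory T cell genes Foxp3 and Ctla4, 4.06% and 4.47%. The effector list was lower in 24 of 27 members (median -0.72, percentile 0), with Gzmf (335 and 84.2 CPM, log2 -1.93), Gzma (-1.70), Gzmc (-1.46) and Serpinb9b (-1.42), an inhibitor of granzymes, among the lowest ratios beside Rgs8 (-1.67) and Tagap1 (-1.43). Within clusters the median was -0.043 in cluster 10, -0.92 in cluster 13 and 0.024 in cluster 20, and it was 0.0066 in male-type cells alone. The class median of -0.72 also depends on the clustering. It lay between -0.48 and -0.36 without a mitochondrial limit, without doublet removal, with 10% left out, at resolutions 0.5 and 2, and with each library clustered alone. Within cluster 10, granzymes chosen after their values had been seen were lower, with Gzmd at 210 and 39.8 CPM, Gzme at 171 and 33.2 CPM, Gzmf at 707 and 354 CPM and Gzmg at 121 and 0 CPM. Gzma had a log2 ratio of -3.96 within cluster 13 (628 and 35.7 CPM), 0.32 within cluster 10 and 0.65 in male-type T-like cells.

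Inflammatory transcripts were higher in T-like cells, with 17 of 18 members of the macrophage inflammatory list (median 1.12, percentile 100). Dissociation and immediate early genes were higher there too, in 18 of 22 (median 0.54, percentile 100), and tissue-resident and regulatory macrophage genes in 15 of 15 (median 0.55, percentile 100), although the latter median was -0.32 within cluster 10 and -0.47 in male-type cells alone. The inflammatory median was 0.43 within cluster 10, 0.63 within cluster 13 and 1.10 within cluster 20. Both-type cells made up 13.4% of T-like cells of the library labelled KO, at a median of 14922 UMIs. Lyz2 of at least 2022 CPM, a level that 95% of WT macrophage or monocyte-like cells reached, was found in 13.5% of WT T-like cells. Macrophage RNA in this class was therefore not separated from transcripts of T cells. The 6 highest ratios were those of Cxcl3 (3.20), Cxcl1 (2.49), Fcrls (2.33), Il1a (2.05), Ccl12 (2.03) and the cytokine gene Il17a (11.8 and 51.2 CPM, log2 1.74), and of these Fcrls, Il1a and Ccl12 were highest in macrophage or monocyte-like cells among the 6 classes. Fcrls came to -0.94 in male-type cells alone, and within cluster 20 the ratios were -0.44 for Il17a, 0.23 for Rgs8 and 1.19 for Gzmc. Cell cycle genes were lower, with 24 of 24 for S phase (median -0.35, percentile 0) and 26 of 27 for G2 and M phase (median -0.41, percentile 0), although the S phase median was 0.14 within cluster 10. Residency and RUNX3-linked genes were split, 12 higher and 12 lower (median -0.01, percentile 71.2), and this median was 0.23 with female-type cells alone.

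Macrophage or monocyte-like cells of the library labelled KO had lower interferon and MHC class II transcripts and higher inflammatory chemokines. Interferon response genes were lower in 30 of 32 (median -0.45, percentile 0), with Irf7, a regulator of interferon genes, at 88.5 and 39.7 CPM and Oasl2 at log2 -0.94. MHC class II genes were lower in 12 of 12 (median -0.45, percentile 0), MHC class I genes in 14 of 15 (median -0.22, percentile 0.02). The inflammatory list was higher in 17 of 20 (median 0.49, percentile 100; 0.37 to 0.94 under the alternatives), with Ccl4 at 452 and 1244 CPM and Ccl2 at log2 0.98. Cytokines that attract NK and T cells were higher in 10 of 16 (median 0.13, percentile 98.8). The largest cluster of this class differed between the libraries: cluster 1, with Ccl8 and Cxcl9, held 10.2% of WT cells and 7.91% of the library labelled KO, and cluster 0, with Fcrls, Folr2 and Pf4, 4.59% and 13.2%. Within its 7 clusters, the inflammatory median lay above 0 in 7, as it did in 25 of 26 clusters of any kind, the MHC class II median below 0 in 7 and the interferon median below 0 in 5. Cluster 2, led by the interferon response genes Rsad2, Ifit3 and Ifit1, held 3.74% of WT cells and 1.79% of the library labelled KO. Within it, 27 of 32 interferon genes were higher (median 0.19). In the 5 clusters below 0, the median ran from -1.09 in cluster 15 to -0.089 in cluster 7, the latter at percentile 45.7. For the class, the interferon median was -0.23 in male-type cells alone and -0.10 with clusters weighted alike, so the mix of clusters carries part of it. Cluster 0 held 6.08% of male-type (4.82 to 7.55%) and 18.8% of female-type cells of the library labelled KO, against 4.59% of WT cells.

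Tissue-resident and regulatory genes were higher in 11 of 17 (median 0.21, percentile 100), with Folr2 at log2 1.26 and Maf at 0.93. Hypoxia and glycolysis genes were lower in 20 of 20 (median -0.37, percentile 0), with Gapdh at log2 -0.53. This list was not compared within clusters. Cluster 4 of this class, with the list members Egln3, Ankrd37 and Bnip3 among its leading genes, held 6.56% of WT cells and 3.58% of the library labelled KO. Cell cycle genes were higher, 23 of 24 for S phase (median 0.30, percentile 100) and 24 of 27 for G2 and M phase (median 0.16, percentile 100), as were dissociation genes in 17 of 22 (median 0.25, percentile 100). The highest gene ratios were Fcrls (72.4 and 289 CPM, log2 1.92), Col14a1 (1.90), Mid1 (1.55), Ccl4 (1.45), Rapgef5 (1.45) and Ctla2a (1.33), of which Fcrls also defines cluster 0. The lowest were Tagap1 (-1.16), the decoy receptor gene Il1r2 (-1.14), Ly6a (-1.07), Irf7 (-1.07), Lyz2 (-1.05) and Oasl2 (-0.94). In male-type cells alone, the resident median was -0.046 and the MHC class I median 0.051.

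Lyz2, which encodes the lysozyme of macrophages, was near background in the male-type cells of the library labelled KO. Macrophage or monocyte-like cells had 9874 CPM of Lyz2 in WT (9839 to 9909), 7253 CPM in female-type cells of the library labelled KO (7208 to 7299) and 153 CPM in its male-type cells (143 to 163). The WT library is male-type as well. Of 516 male-type cells of this class in the library labelled KO, 1 reached the level of 2022 CPM that 95% of WT cells reached, and 85.6% of 1277 female-type cells did. Male-type cells were as low in cluster 0 (180 CPM), cluster 1 (140 CPM) and cluster 5 (137 CPM), where WT had 11516, 9882 and 12440 CPM. NK-like cells, which should lack Lyz2, had 130 CPM in female-type and 125 CPM in male-type cells of the same library. The log2 ratio of Lyz2 to WT in macrophage or monocyte-like cells, -1.05 over all cells of the class, was -5.95 with male-type and -0.44 with female-type cells. This split by sex type was looked at after the alternatives had been computed.

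**Figure D4:**
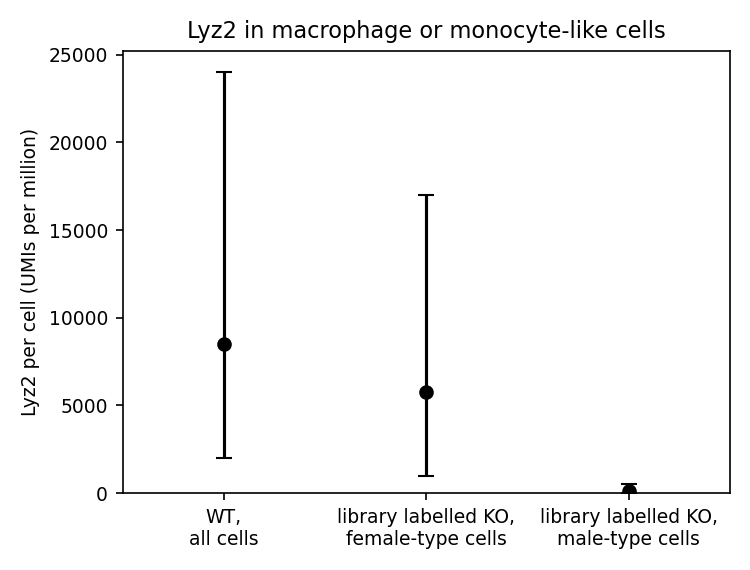
Lyz2 per cell in UMIs per 1000000 (vertical axis) in macrophage or monocyte-like cells of WT and of the female-type and male-type cells of the library labelled KO. Points are medians over cells and bars run from the 5th to the 95th percentile of cells; the medians are 8487, 5766 and 119.

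In fibroblast-like cells, inflammatory genes were higher and interferon genes lower in the library labelled KO. The inflammatory list was higher in 17 of 18 (median 0.83, percentile 100), the interferon list lower in 28 of 32 (median -0.36, percentile 0), and the list of cancer-associated fibroblast and matrix genes higher in 16 of 27 (median 0.19, percentile 100). Tnc, Col1a1, Col1a2 and Postn of the matrix list are leading genes of cluster 17, which has 4 cells per library. The median of that list was not taken within cluster 16 alone. Macrophage transcripts were higher in these cells too: tissue-resident and regulatory macrophage genes were higher in 13 of 15 (median 0.63, percentile 100). In cluster 16, Tyrobp, a leukocyte gene, was at 0.0849 of the macrophage or monocyte-like level in WT and 0.126 in the library labelled KO. The 6 highest genes included Cxcl3 (3.92), F13a1 (2.56), S100a9 (2.13) and Pf4 (2.06), of which F13a1 and Pf4 were highest in macrophage or monocyte-like cells, and a single cell held 85.1% of the Cxcl3 and 83.8% of the S100a9 UMIs of the class in the library labelled KO. The other 2, the matrix gene Tnc (2.74) and Cxcl14 (2.31), came mostly from the 4 cells per library of cluster 17, with 98.6% and 94.7% of their UMIs in the library labelled KO, and Tnc was at -0.22 within cluster 16. The lowest were Mgp (246 and 48.0 CPM, log2 -2.24), an inhibitor of calcification found in 18 and 15 cells, and Lbp (-1.25), Flt1 (-1.17), Usp18 (-1.04), Slco3a1 (-1.04) and Clec3b (-1.02). In WT, a single cell held 53.2% of the Mgp and 58.5% of the Flt1 UMIs, and cluster 17 held 42.4% of Mgp UMIs in WT and 89.6% in the library labelled KO.

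Dendritic-like cells had higher Cxcl3 (2.82), Slpi (1.48) and Tnfsf9 (1.41) in the library labelled KO. Their lowest ratios were those of Gzmc (-3.71), Xcl1 (-2.93) and Styk1 (-1.97), which are NK cell transcripts. Mast or basophil-like cells, 40 in WT and 26 in the library labelled KO, had 1 and 72 UMIs of Areg (log2 5.66), which encodes amphiregulin, and a log2 ratio of -3.97 for the basophil protease gene Mcpt8. Speer4e (2.95) and AA467197 (2.69) were the other highest, Vegfc (-3.48) and C1qa (-1.82) the other lowest.

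The library labelled KO held transcripts of both sexes. Its cells had 716 CPM of Xist and 104 CPM of the 4 Y-linked genes, against 0.0395 and 299 CPM in WT, and 54.7% of them were female-type, 24.1% male-type and 8.07% both-type, whereas 79.5% of WT cells were male-type.

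**Figure D5:**
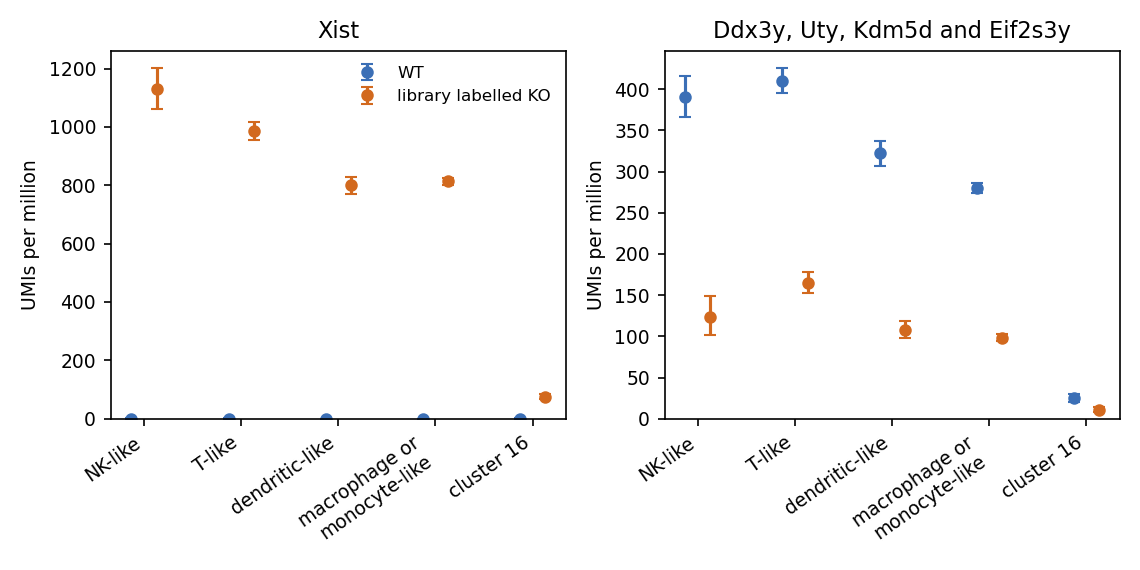
Xist (left) and the sum of Ddx3y, Uty, Kdm5d and Eif2s3y (right) in UMIs per 1000000 (vertical axes) for 4 classes and for cluster 16, in WT (blue) and the library labelled KO (orange), with exact Poisson 95% intervals as bars. Xist is near 0 in WT, and Y-linked genes are lower in the library labelled KO and lowest in cluster 16, at 24.6 and 10.99 CPM.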

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

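All tests of explanations in this part were chosen after the results they measure had been seen.

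The library labelled KO holds cells of both sex types while WT holds male-type cells, a signal in genes that the comparisons leave out. Xist, the RNA of the inactive X chromosome, had 716 CPM over all cells of the library labelled KO and 0.0395 CPM (3 UMIs) in WT, and the 4 Y-linked genes had 104 and 299 CPM. Of 5194 cells in the library labelled KO, 2840 were female-type, 1250 male-type, and 419 (8.07%) had UMIs of Xist and of a Y-linked gene, at a median of 16437 UMIs. Female-type and male-type cells of that library had medians of 9294 and 10090.5 UMIs. The both-type cells, kept after doublet removal, made up 34.7% of cluster 11 and 23.3% of cluster 20 in that library. Cluster 11 had the highest mean doublet score of any cluster (0.106). It scored highest for macrophage or monocyte markers, yet Cd8a and Cd3g were among its leading genes. The mean score of cluster 20 was 0.0533. Doublets that the filter left are a candidate source of both-type cells, which was not tested.

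Cells of at least 1 male and 1 female animal in that library may explain the mixture: the male-type share of cells called male or female was 30.6% overall and, in NK, T, macrophage or monocyte and dendritic-like cells, at most 2.86 percentage points away. Barcodes carried over from WT are argued against, because 3 of 1250 male-type cells (0.24%, 0.0495 to 0.700%) have a barcode of the WT library. For WT cells mixed into the suspension, the slope of male-type on female-type differences from WT over 8763 genes was 0.397 (0.303 to 0.417), between the bounds written for it, and left the question open. Lyz2, looked at after that, argues against such cells: 0.194% of male-type macrophage or monocyte-like cells (0.00491 to 1.08%) reached the level that 95% of WT cells reached. A difference in sex as the whole source of the lower NK-like share is argued against, because with male-type cells of both libraries the ratio was 0.428 (0.267 to 0.655). The effector median over all cells was then -0.50. Other differences between the animals were not tested and stay open as a source of any difference between the libraries, as does sex for values that came near 0 in male-type cells, such as the effector median in T-like cells (0.0066).

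A library-wide signal was also found in the barcodes below the UMI minimum: 1053 barcodes (16.02%) of the library labelled KO had under 500 UMIs and 0 of WT did, with 5.95% mitochondrial UMIs against 0.504% over all its barcodes. Igkc, an antibody light chain gene that the naming rule leaves out, had 1842 CPM in the library labelled KO and 69.4 CPM in WT, with 98.6% and 94.0% of its UMIs in cluster 27.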

How the results depend on the processing

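The alternatives by sex type, by 10% doublets, with clusters weighted alike and with single T-like clusters were chosen after seeing the data; the others were planned. No paired analysis was possible because each group has 1 library. Over the 22 main results, 190 of 257 alternatives stayed within the counting interval. The value lay on the other side of no difference in 33, of which 31 concern results whose interval held no difference, such as the RUNX3-linked median of -0.01 in T-like cells, and 2 the effector median in T-like cells. Over 121 others, 1709 of 1735 alternatives kept the direction, and for the 84 gene results 1194 of 1210. These genes were named for the size of their ratio in the same counts, which favours a kept direction. Neither another pseudocount nor a higher UMI minimum can reverse the ratio of a gene. The counts of kept directions therefore say little about how firm the gene results are. The NK-like share ratio of 0.473 stayed between 0.428 and 0.555. The alternatives counted include the per-cell gates, which could not be set apart from their background for NK cells. Library-by-library clustering gave no neutrophil-like ratio. Except where stated, the cause was not tested.

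Without a mitochondrial limit, the T-like share ratio was 0.609, the effector median in T-like cells -0.40, their RUNX3-linked median 0.18, and the macrophage interferon and inflammatory medians -0.37 and 0.60. The limit left out 0 barcodes of WT and 7 of the library labelled KO, too few to move these values by themselves. The cells were also clustered anew in this setting, so the shifts show how far the values depend on the clustering. Without doublet removal, NK-like Runx3 was 0.048, the effector median -0.064 in NK-like and -0.48 in T-like cells, the RUNX3-linked T-like median 0.18 and Ms4a6c in NK-like cells 0.15. With 10% left out, the macrophage share ratio was 1.15, the T-like effector median -0.46 and the macrophage inflammatory median 0.82. Resolution 0.5 gave 1.22, -0.36 and 0.94 for these. Resolution 2 gave a T-like effector median of -0.42, a RUNX3-linked median of 0.20, a resident macrophage median of -0.16 in T-like cells, and macrophage interferon and inflammatory medians of -0.38 and 0.62. Each library clustered alone gave a macrophage share ratio of 0.974, a T-like effector median of -0.45, and macrophage interferon and inflammatory medians of -0.33 and 0.37.

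In male-type cells, the neutrophil-like ratio was 27.8. Runx3 was -0.30 in all, 0.62 in NK-like, -0.11 in T-like and -0.19 in macrophage-like cells. The effector median was -0.50 in all, 0.13 in NK-like and 0.0066 in T-like cells. The macrophage interferon median was -0.23, MHC class I 0.051 and resident genes -0.046. In NK-like cells inhibitory receptors were -0.23, Fabp5 -0.26, Ccl1 -1.11, H2ac8 -2.73 and Prss2 -1.73, and in T-like cells Fcrls -0.94, Gzma 0.65 and resident macrophage genes -0.47. With female-type cells of the library labelled KO, the macrophage, neutrophil and fibroblast-like ratios were 1.17, 5.04 and 0.504, the last set by the subset itself, since 66.9% of fibroblast-like cells there have no sex call. Runx3 was -0.46 in all and -0.49 in macrophage-like cells, the WNT median -0.015, the NK-like effector median 0.12, Fabp5 -0.12, the RUNX3-linked T-like median 0.23, and the macrophage interferon and inflammatory medians -0.56 and 0.43. Without both-type cells, Runx3 was -0.45 in all and -0.36 in T-like cells, the effector median 0.13 in NK-like and -0.46 in T-like cells, and Fabp5 in NK-like cells -0.14.

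Scaling without the 50 most abundant genes gave -0.64 for effectors over all cells and -0.49 for macrophage interferon genes. A pseudocount of 1 CPM gave -0.76 and -0.49 for these and 0.63 for macrophage inflammatory genes, and 20 CPM gave -0.34, -0.30 and 0.39, with -0.63 for T-like effectors; a larger pseudocount shrinks ratios by construction. With clusters weighted alike, Runx3 was -0.17 in T-like and -0.26 in macrophage-like cells, the T-like effector median -0.37, and the macrophage interferon and inflammatory medians -0.10 and 0.57, so the mix of clusters carries part of each of these values but the last. Taken alone, clusters 10, 13 and 20 gave Runx3 of -0.083, -0.34 and -0.11 and effector medians of -0.043, -0.92 and 0.024. Cluster 10 gave 0.14 for S phase, 0.32 for Gzma and -0.32 for resident macrophage genes, and cluster 20 -0.44 for Il17a, 0.23 for Rgs8 and 1.19 for Gzmc. Thinned to 1000 UMIs per cell, the ratio of cells with a Runx3 UMI was 0.769 over all and 0.793 in T-like cells, against 0.906 and 0.927 unthinned. Depth limits the NK-like comparison, with 99 cells in the library labelled KO.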

Other observations

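All tests of explanations in this part were chosen after the results they measure had been seen.

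Male-type and female-type cells of the library labelled KO differed in their share of cluster 0, which is led by Fcrls, Cbr2, Folr2 and Pf4, genes of resident macrophages, and held 18.8% of female-type (17.3 to 20.3%) and 6.08% of male-type cells (4.82 to 7.55%). The clustering did not bar Xist, the Y-linked genes or Lyz2, which differ between the sex types, so cluster shares may partly reflect those genes. The intervals overlapped for neutrophil-like cells (0.845%, 0.542 to 1.25%, and 1.68%, 1.04 to 2.56%), for cluster 8 (3.73%, 3.07 to 4.50%, and 5.2%, 4.04 to 6.58%), for cluster 3 (4.37% and 4.88%), for the CD8 T cell cluster 10 (2.46% and 3.92%) and for T-like cells as a class (9.05% and 10.3%). In each of these sets the male-type share was the higher, and overlapping intervals do not show that the shares were alike.

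In NK-like cells, the Runx3 level was not lower in the library labelled KO than in WT, at 846 and 691 CPM. Free RNA is argued against, because NK-like cells of that library had 37.8 times (30.3 to 47.5) the Runx3 CPM of its fibroblast-like cells. Runx3 UMIs from cells of 1 sex type alone are argued against as well. In NK-like cells, the sex type with the lower level still had 1.15 times (1.03 to 1.28) the WT level. Whether cells of only 1 sex carry the deletion stays open, because the counted tags may lie outside the deleted part. Counts from a part of the gene that the deletion leaves, and a library that is not a knockout, cannot be told apart, because both allow the observed ratio of 1.22 (1.12 to 1.33) and the counts are per gene.

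Lyz2 near background in male-type cells of the library labelled KO, where 0.194% of macrophage or monocyte-like cells reached the WT range against 95% of WT cells, may reflect the genotype of the male animal. Candidate explanations are an altered Lyz2 allele, as in strains with Cre recombinase inserted into Lyz2, and a sequence variant that the counting misses. Neither was tested, and the labels name no such allele. A Cre strain of this kind would delete a conditional gene in myeloid cells, and Runx3 in macrophage or monocyte-like cells was 189 CPM in male-type and 150 CPM in female-type cells, against 212 CPM in WT. These counts cannot show or exclude a deletion that leaves the counted part of the gene.

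The fibroblast-like cells of cluster 16, with Col3a1, Sparc and Dcn but also Hmga2 and Sox9 among their leading genes, had few UMIs of Xist or Y-linked genes in either library. Neither was found in 79.9% of its WT cells and 68.5% of its cells in the library labelled KO, and Y-linked genes had 24.6 and 10.99 CPM. WT cells of cluster 16 were deeper than WT macrophage or monocyte-like cells, at medians of 15024 and 8862.5 UMIs. Low Y-linked levels of fibroblasts in general are argued against by cluster 17, whose 4 WT cells had 16 such UMIs, 1.41 times (0.803 to 2.28) the macrophage level. Cells with no Y chromosome and no Xist that take up leukocyte RNA may explain it: the Y-linked level was 0.0879 of the macrophage level, within the 0.0704 to 0.0970 of leukocyte genes, so implanted tumour cells are a candidate source, which the labels do not name.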
